A study of Mus musculus with 15 samples.

How the data were processed

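Whole hippocampus from adult female mice was profiled on 15 1-colour (Cy3) arrays, 5 each from sedentary SAMR1, sedentary SAMP8 and exercised SAMP8, grouped per the labels. The labels give neither the kind and length of the exercise nor the ages. Total RNA was extracted and Cy3-labelled cRNA was prepared from it, per the labels' protocols. The scanner, feature extraction, background step and array filter are not given in the sources used here. The deposited values are intensity values on a linear scale, from 4.02 to 65480, 1 column per array. Per the submitters' processing notes limma was used, with no version or step named. The sorted values of the 15 columns were nearly identical, as quantile normalization between arrays leaves them, and this normalization is read from the values. The scale and the between-array centring are thus known from the values, there is no direction to settle on 1-colour arrays, and the background subtraction stays unknown.

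The deposited table had 45220 rows, of which 10741 (23.8%) had no value on any array and 34479 had values on every array. The filter behind the empty rows is not given in the sources used here. The median intensity of the SAMR1 arrays, replicates 1 to 5, was 208.67, 208.17, 208.62, 208.57 and 207.88. That of the sedentary SAMP8 arrays was 208.65, 207.75, 208.23, 208.37 and 208.25. That of the exercised SAMP8 arrays was 208.22, 208.17, 208.25, 208.22 and 208.29. No pair of arrays shared more than 0.125% of identical values. The number of arrays, 5 per group, limits the precision.

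Feature numbers were paired with genes through the platform annotation table. Of the features with values, 27968 had 1 gene symbol, 38 had several and 6473 were not listed there. The 6511 without a single symbol were left out of gene counts and tested apart. For each of 16401 genes the probe with the highest mean over all arrays was used, and 6970 genes had several probes. In the text the array features of the leading genes are 7974 for Ccl19, 23532 for Adat2, 33249 for Slc2a5, 32423 for Ppp1r1a, 26871 for Enpp5 and 33503 for Usf1. Intensities under the 5th percentile of all values, 39.17, were raised to that floor before taking log2. Between 3.54% and 4.57% of the gene values of an array lay at the floor. Values as deposited were otherwise unchanged, and the probe filter on brightness was none.

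Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 fit of all 15 arrays with 1 term per group. Calls were made at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over the 16401 genes. The contrasts were sedentary SAMP8 minus SAMR1, exercised minus sedentary SAMP8, and, as a secondary one, exercised SAMP8 minus SAMR1. Standard errors are those of the fit. The named genes were taken by a rule fixed before the data were examined. It took up to 12 genes higher and 12 lower with the largest change among called genes with a mean above the median gene and groups that did not overlap, and 5 each way for the secondary contrast. Where fewer than 5 passed in a direction it took the 5 with the lowest p. It also took up to 4 members of each list named, those with the lowest p, and allowed every called member of a list. Predicted genes without a characterised name were passed over.

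Before the data were examined, 42 gene lists were written down, covering cell type and region markers and pathways of synapses, metabolism, stress, immunity and exercise, with 872 measured genes. List members were matched by symbol, or by a synonym naming 1 gene in the RefSeq table. Some list members had no value here and are not reported. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 42 lists. Camera with a correlation estimated per list and fry, which tests whether a list's genes move on balance one way, were alternatives. The mean of each list per array was compared between groups by an exact two-sided permutation test of all splits of 10 arrays. The smallest possible p is 0.00794, and p was adjusted over the 42 lists within a comparison. The test ignored any pairing of arrays, so for the paired sedentary arrays its p-values are not exact. Adjustment over the list alone repeated the Benjamini-Hochberg step within each list.

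The order of genes was taken from the RefSeq table of assembly GRCm38.p6, in which 16373 of the tested genes had a position, and it was used only to find neighbours. The share of called genes with a called gene among the 5 nearest tested genes on either side was compared with 10000 random draws, one-sided. Regroupings of arrays, 100 per comparison, and splits of shared arrays refitted the model each time.

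The replicate numbers shared between groups were checked for pairing before the calls of the fits were compared. Deviations from the group means of same-numbered sedentary SAMR1 and SAMP8 arrays correlated across genes in 5 of 5 pairs (r = 0.27, 0.23, 0.38, 0.52 and 0.42), each array best with its own number, so the numbers were taken to pair this comparison. The labels do not say what a number marks.

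The scripts were tested on simulated data with 16401 independent genes, of which 50 per size were changed by known folds. In the comparison of the sedentary lines the test recovered 18% of genes changed 1.25-fold, 44% at 1.5-fold, 96% at 2-fold and 90% at 3-fold, with 8 false calls. For exercise it recovered 12%, 66%, 86% and 94%, with 6 false calls, and for exercised SAMP8 against SAMR1 it recovered 6%, 56%, 90% and 90%, with 7.

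Alternatives fixed before the data were examined were median centring, quantile normalization, the mean of all probes of a gene, leaving out the dimmest 40% of genes, a mean-variance trend with a robust prior, array quality weights, only the compared groups, the replicate number as a block, a floor at the 20th percentile (63.65), other thresholds, counting by probe, and leaving out each array in turn. Cyclic loess between arrays, the sedentary arrays alone with a replicate block, choroid plexus and meningeal marker means as covariates, and the meningeal mean as a covariate within pairs were chosen after seeing the data. Arrays far from the other 4 of their group were sought by Dixon's ratio of gap to range, with a critical value of 0.710, in the group means of 15 marker lists and in 81 named genes. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.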

Results

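Expression was measured in the whole hippocampus of adult female mice from a pair of inbred lines. SAMP8 is a senescence-accelerated line known for early learning and memory deficits, and SAMR1 is its senescence-resistant counterpart. The 15 arrays fell into 3 groups of 5: sedentary SAMR1, sedentary SAMP8 and SAMP8 that had exercised. The labels number the 5 arrays of a group as biological replicates without saying whether each came from 1 animal, so the p-values measure the spread between these samples. Values were obtained for 16401 named genes on every array, and the 15 arrays had nearly the same median intensity. The number of arrays limited the precision, with a median standard error of 0.12 on the log2 scale for a difference between groups.

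The first comparison asked how the hippocampus of sedentary SAMP8 mice differed from that of sedentary SAMR1 mice. Among the 16401 named genes the widest difference was in Ccl19, a chemokine that attracts T cells and dendritic cells, which was 48.8-fold higher in SAMP8 (log2 difference 5.61 ± 0.25, SE, n = 5 per group, adjusted p = 4.58e-10). Adat2, the catalytic subunit of a tRNA adenosine deaminase, was 5.50-fold higher (2.46 ± 0.10), and Slc2a5, a fructose transporter, was 4.38-fold higher (2.13 ± 0.16). In the other direction, Ppp1r1a, an inhibitor of protein phosphatase 1, was 6.70-fold lower in SAMP8 (log2 difference -2.75 ± 0.17). Enpp5, a member of the ectonucleotide pyrophosphatase family, was 3.76-fold lower (-1.91 ± 0.13), and the transcription factor Usf1 was 3.09-fold lower (-1.63 ± 0.09). In each of these 6 genes all 5 arrays of one group lay above all 5 of the other. The RefSeq gene table of the GRCm38.p6 assembly also lists pseudogene copies of Ccl19, and whether the probe also reads these was not tested.

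**Figure D1:**
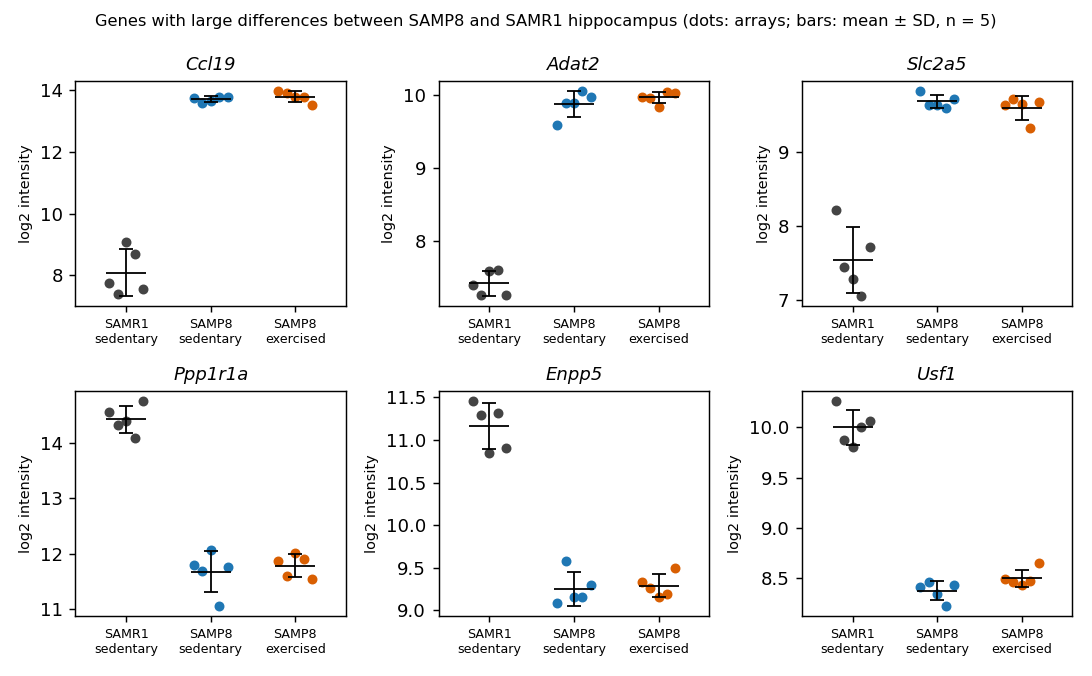
Log2 intensity of 6 genes on each of the 15 arrays, by group, with bars for the mean ± SD (n = 5). Ccl19, Adat2 and Slc2a5 were higher and Ppp1r1a, Enpp5 and Usf1 lower in all 10 SAMP8 arrays than in all 5 SAMR1 arrays.

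In all, 431 of the 16401 genes (2.63%) differed between the sedentary lines, 240 higher and 191 lower in SAMP8. At least 2-fold differences were found in 86 of them, 46 higher and 40 lower. The median size of the 431 differences was 0.66 on the log2 scale. Among the more strongly expressed genes, further large increases in SAMP8 were found in Rpusd4, a mitochondrial pseudouridine synthase (3.46-fold, 1.79 ± 0.10), Zfp667, a zinc finger protein (3.32-fold, 1.73 ± 0.17), and Fbll1, a fibrillarin-like protein (3.27-fold, 1.71 ± 0.08). Mal2, a membrane protein of vesicle transport, was 2.85-fold higher (1.51 ± 0.11), Dctn3, a subunit of dynactin, 2.64-fold (1.40 ± 0.09), and the protein kinase Uhmk1 2.57-fold (1.36 ± 0.10). Ccn2, a matrix-associated growth factor, was 2.49-fold higher (1.32 ± 0.22). Lower in SAMP8 were Mcur1, a regulator of mitochondrial calcium uptake (2.74-fold, -1.46 ± 0.18), the cell adhesion gene Pcdh9 (2.73-fold, -1.45 ± 0.18), Auh, an enzyme of leucine breakdown (2.65-fold, -1.41 ± 0.10), and the membrane glycoprotein Emb (2.56-fold, -1.36 ± 0.13). Mrpl41, a protein of the mitochondrial ribosome, was 2.47-fold lower (-1.31 ± 0.09), Mpeg1, a macrophage pore-forming protein, 2.47-fold (-1.30 ± 0.11), and the extracellular matrix protein Thbs4 2.44-fold (-1.29 ± 0.25). Uchl4 and Uap1l1 were 2.30-fold (-1.20 ± 0.16) and 2.28-fold (-1.19 ± 0.12) lower. The adjusted p-values of these 16 genes ran from 1.08e-09 for Fbll1 to 0.00683 for Thbs4. The same-numbered sedentary arrays of the lines deviated together, and a fit of those 10 arrays with the replicate number as a block, chosen after the data were seen, called 648 genes. The block over all 15 arrays, chosen before, called 460. The choroid plexus and meningeal marker means were added as covariates after the data were seen. They widened the median standard error from 0.12 to 0.17, which alone ends some calls. Ccn2 (0.89 ± 0.31, adjusted p = 0.361) and Thbs4 (-1.19 ± 0.38, adjusted p = 0.272) lost their calls with them, Thbs4 at nearly the same difference. Pcdh9 lost its call when all its probes were averaged (-0.03, adjusted p = 0.958).

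The genes that differed lay close together in the genome. Of the 430 called genes with a position in the reference table, 226 (52.6%) had another called gene among the 5 nearest tested genes on either side, against a mean of 23.3% in 10000 random draws of as many genes (one-sided permutation p = 1e-04, the smallest these draws can give). Among the 24 genes with large differences named for this comparison, 12 had a called neighbour: Ccl19, Ccn2, Dctn3, Emb, Fbll1, Mrpl41, Rpusd4, Uap1l1, Uchl4, Uhmk1, Usf1 and Zfp667. Called genes formed 32 groups of 3 or more, which held 132 genes. A pair of groups held 7 genes each. The first was Rpp25l, Dctn3, Ccl27a, Gm3893, Ccl19, Vcp and Fancg, with 6 of 7 higher in SAMP8, and the second was Adnp2, Rbfa, Txnl4a, Slc66a2, Kcng2, Nfatc1 and Zfp236, with 5 of 7 higher. Usf1 lay in a group with Ppox, Usp21 and Nit1, and Mrpl41 in a group with Zmynd19, Dph7 and Nrarp. Genes with an unadjusted p under 0.05 for exercise showed no such neighbourhood, with 30.5% against 29.7% at random (one-sided permutation p = 0.369). There were 573 genes at that p, against 820 expected by chance, and none was called, so they could hardly differ from random genes. They do not show that the neighbourhood is particular to the lines. Of the genes called between exercised SAMP8 and SAMR1, 51.5% had a called neighbour, against 30.5% at random (one-sided permutation p = 1e-04). That comparison shares the SAMR1 arrays.

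Interferon-stimulated genes were higher as a group in sedentary SAMP8. Of the 25 measured members, 9 were higher, none was lower and 16 did not pass, and adjusted over the list alone 13 were higher. They included Eif2ak2, the double-stranded RNA-activated kinase PKR (0.77 ± 0.12, adjusted p = 0.00072), Ifi27l2a (1.48 ± 0.27, adjusted p = 0.00383), Parp14 (0.69 ± 0.13, adjusted p = 0.00354) and the RNA sensor Ifih1 (0.52 ± 0.10, adjusted p = 0.00764). The list's mean was 7.75 ± 0.23 (SD, n = 5) in SAMP8 and 7.30 ± 0.08 in SAMR1, with no overlap. The exact two-sided permutation p was 0.00794, the smallest that 5 against 5 can give, and 0.111 after adjustment over the 42 lists. Here and for the lists below between these lines, that test ignored the pairing of same-numbered sedentary arrays. The list passed camera (adjusted p = 1.91e-13) but not with an estimated correlation (adjusted p = 0.213). The other 5 called members were Usp18 (0.94 ± 0.22), Oasl2 (0.78 ± 0.19), Rtp4 (0.66 ± 0.16), Oas2 (0.61 ± 0.15) and Oas1a (0.48 ± 0.12). Each lost its call when certain single sedentary arrays were left out: Usp18 without SAMR1 replicate 1 or 2 or SAMP8 replicate 3 or 4 (adjusted p up to 0.0835), Rtp4 without those or SAMR1 replicate 5 (up to 0.0882), Oasl2 without any SAMR1 array or SAMP8 replicate 3 or 4 (up to 0.0873), and Oas2 and Oas1a without any one sedentary array except SAMR1 replicate 4 or SAMP8 replicate 2 (up to 0.091 and 0.11). With the choroid plexus and meningeal marker means as covariates, Eif2ak2 alone of the 9 kept its call (0.80, adjusted p = 0.0306), while the list still passed camera (adjusted p = 0.00112). The differences of the other 8 were smaller with them, from 29.3% of the size for Usp18 (0.28 ± 0.23) to 59% for Ifi27l2a (0.87 ± 0.36). Parp14 (adjusted p = 0.56), Ifih1 (0.211) and Oas2 (0.27) also lost their calls when all probes of a gene were averaged. A floor at the 20th percentile ended the calls of Oas2 (0.13, adjusted p = 0.691), Oas1a (0.071), Usp18 (0.0673), Oasl2 (0.0665) and Rtp4 (0.0568). A fit of only the compared groups ended those of Rtp4 (0.0833), Usp18 (0.0764) and Oasl2 (0.0705), and the block over all arrays those of Oas2 (0.0609) and Oasl2 (0.0506). Array weights ended the call of Rtp4 (0.0843), and a variance trend with a robust prior that of Oas1a (0.0546). Of the 9 called members, 3 (Eif2ak2, Ifih1 and Usp18) had a called neighbour in the genome.

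Markers of pericytes and smooth muscle, the contractile cells of vessel walls, were also higher in sedentary SAMP8. Of 15 measured members 6 were higher and 9 did not pass, and adjusted over the list alone 8 were higher. They included the growth factor receptor Pdgfrb (0.82 ± 0.12, adjusted p = 0.000395), Rgs5 (0.63 ± 0.12, adjusted p = 0.00759), Vtn (0.88 ± 0.18, adjusted p = 0.00917) and Cnn1, the muscle protein calponin (1.48 ± 0.33, adjusted p = 0.0172). The list's mean was 8.94 ± 0.12 (SD, n = 5) in SAMP8 and 8.48 ± 0.25 in SAMR1 (exact two-sided permutation p = 0.00794, 0.111 after adjustment). It passed camera (adjusted p = 7.82e-07) but not with an estimated correlation (adjusted p = 0.213). Cnn1 lost its call without SAMR1 replicate 1, 2 or 5 or sedentary SAMP8 replicate 1 or 4 (adjusted p up to 0.0547). Kcnj8 (0.43 ± 0.10) lost it without SAMR1 replicate 2, 3 or 4 or sedentary SAMP8 replicate 1, 3, 4 or 5 (up to 0.0919), and Anpep (0.67 ± 0.17) without any one of 12 arrays, all but SAMR1 replicate 3 and exercised SAMP8 replicates 4 and 5 (up to 0.116). With the choroid plexus and meningeal marker means as covariates none of the 6 kept its call, while the list still passed camera (adjusted p = 0.00309). Pdgfrb (0.69 ± 0.18, adjusted p = 0.0992), Rgs5 (0.62 ± 0.18, adjusted p = 0.214) and Kcnj8 (0.55 ± 0.15, adjusted p = 0.157) kept most of their difference or more, with wider standard errors. Those of Vtn (0.38 ± 0.20, adjusted p = 0.756), Cnn1 (0.49 ± 0.32, adjusted p = 0.873) and Anpep (0.34 ± 0.21, adjusted p = 0.849) were smaller. Rgs5 also lost its call in the block fit of the sedentary arrays (adjusted p = 0.0526), and Rgs5 (0.0732) and Kcnj8 (0.365) when all probes of a gene were averaged. Kcnj8 lost it with the block over all arrays (0.0582), Anpep with a floor at the 20th percentile (0.0749) and Cnn1 in a fit of only the compared groups (0.0568). Of the 6 called members, 3 (Cnn1, Kcnj8 and Rgs5) had a called neighbour in the genome.

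Markers of the meninges and fibroblasts were higher in sedentary SAMP8 too, and the list does not tell meninges from fibroblasts. Their mean was 9.70 ± 0.35 (SD, n = 5) in sedentary SAMP8 and 8.88 ± 0.52 in SAMR1 (exact two-sided permutation p = 0.0397, 0.278 after adjustment), with 17 of 18 members higher. The list passed camera (adjusted p = 2.81e-10) but not with an estimated correlation (adjusted p = 0.405). The collagen genes Col1a1 (1.36 ± 0.23, adjusted p = 0.00176), Col3a1 (1.35 ± 0.27, adjusted p = 0.00764) and Col1a2 (0.99 ± 0.23, adjusted p = 0.027) and Aldh1a2, which makes retinoic acid (1.57 ± 0.39, adjusted p = 0.0418), were higher, 14 members did not pass, and adjusted over the list alone 11 were higher. Col1a2 lost its call without SAMR1 replicate 1, 2 or 5 or sedentary SAMP8 replicate 1, 2 or 3 (up to 0.0868). Aldh1a2 lost it without any one of 11 arrays, all but SAMR1 replicates 3 and 4 and exercised SAMP8 replicates 4 and 5 (up to 0.128). Col1a2 also lost it with only the compared groups (0.0562) and a floor at the 20th percentile (0.0627), and Aldh1a2 with these (0.0838 and 0.0978), the block over all arrays (0.0661) and a variance trend with a robust prior (0.0913). Choroid plexus and ependyma markers were lower in SAMP8 as a list (camera adjusted p = 0.00195), with 19 of 22 members lower and no member called, 0 also when adjusted over the list alone. Their mean was 8.42 ± 0.78 in SAMP8 and 9.01 ± 0.49 in SAMR1 (exact two-sided permutation p = 0.183). The list did not pass with an estimated correlation (adjusted p = 0.775) or without sedentary SAMP8 replicate 5 (adjusted p = 0.11). It passed camera in the block fit of the sedentary arrays, chosen after the data were seen (adjusted p = 2.89e-07), and of all arrays (0.00892). With both marker means as covariates, the fit called 179 genes between the lines, 79 higher and 100 lower, and the 4 called members, themselves part of the covariate, lost their calls: Col1a1 (0.54 ± 0.14, adjusted p = 0.106), Col3a1 (0.57 ± 0.14, adjusted p = 0.0857), Col1a2 (0.45 ± 0.21, adjusted p = 0.669) and Aldh1a2 (0.10 ± 0.21, adjusted p = 0.991).

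**Figure D2:**
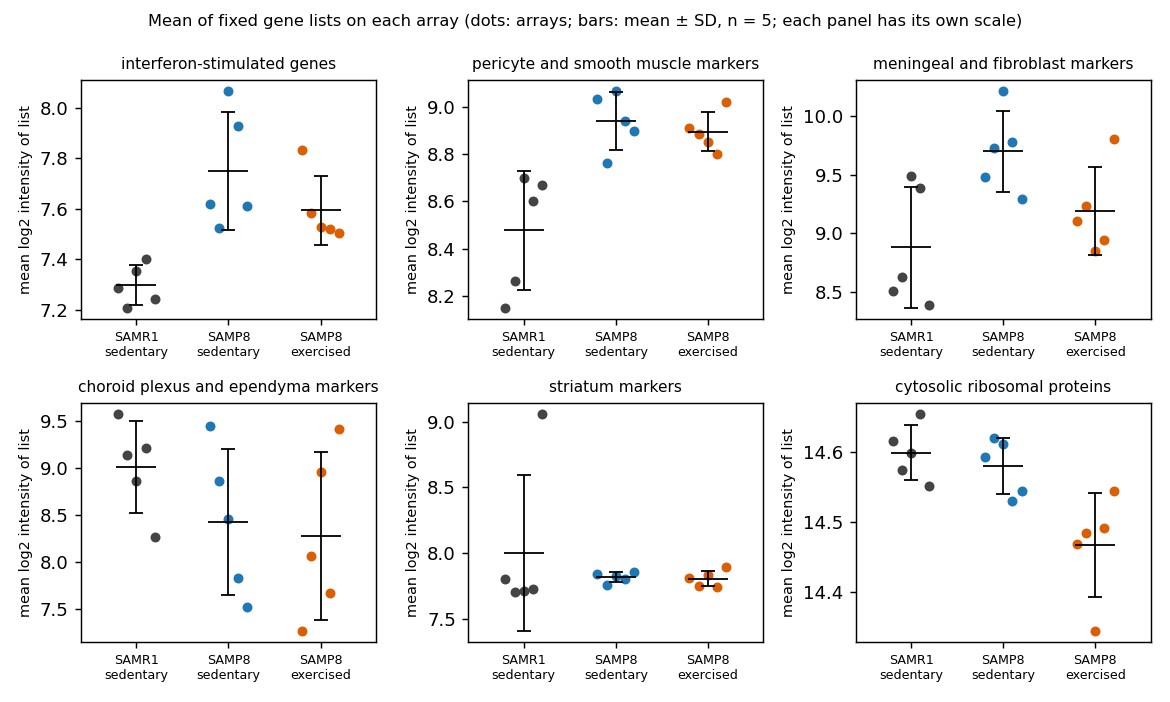
Mean log2 intensity of 6 fixed gene lists on each array, by group, with bars for the mean ± SD (n = 5) and a separate scale for each panel. The interferon and pericyte lists were higher in every sedentary SAMP8 array than in every SAMR1 array, and SAMR1 replicate 5 stood apart in the striatum markers.

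A further 3 lists passed camera at an adjusted p of 0.0263, each higher in SAMP8 and each with few called members. By their means per array the exact two-sided permutation p, unadjusted, was 0.0714 for the endothelial list. It was 0.294 for the immediate early list and 0.0556 for the senescence list. Of the 19 endothelial markers, the drug efflux transporter Abcb1a was higher (1.28 ± 0.07, with 4 of 5 SAMR1 arrays at the floor value, so that its size depends on the floor), the thyroxine transporter Slco1c1 was lower (-0.66 ± 0.14) and 17 did not pass, and adjusted over the list alone 3 were higher and 1 lower. The endothelial list lost its call in the block fit of the sedentary arrays (adjusted p = 0.0687, and 0.0498 with the block over all arrays), with an estimated correlation (adjusted p = 0.682), without the dimmest 40% of genes (adjusted p = 0.654), with the choroid plexus and meningeal covariates (adjusted p = 0.176), and without SAMR1 replicate 1 or sedentary SAMP8 replicate 1 (up to 0.193). Slco1c1 lost its call without SAMR1 replicate 1 or 5 (up to 0.0547) and with those covariates (-0.24 ± 0.15, adjusted p = 0.86). Among 25 activity-regulated immediate early genes, the transcription factor Klf4 was higher (0.55 ± 0.14, adjusted p = 0.0356) and 24 did not pass, with 1 higher when adjusted over the list alone. That list did not pass with an estimated correlation (adjusted p = 0.775) or without SAMR1 replicate 3 or 4 or sedentary SAMP8 replicate 2 or 5 (up to 0.336). It passed with the choroid plexus and meningeal covariates (adjusted p = 1.46e-16) and in the block fit of the sedentary arrays (0.0146) and of all arrays (0.0355). These camera values rest on the preset correlation of 0.01, whereas the correlation estimated for this list without covariates was 0.491. Its mean was 9.807 ± 0.254 (SD, n = 5) in SAMP8 and 9.565 ± 0.444 in SAMR1. Klf4 lost its call without SAMR1 replicate 3, 4 or 5 or any one sedentary SAMP8 array (up to 0.106), in the block fit of the sedentary arrays (0.0587) and of all arrays (0.0783), with only the compared groups (0.0686) and with a floor at the 20th percentile (0.0568). Of 17 genes of cell senescence and cell cycle arrest, the cyclin-dependent kinase inhibitor Cdkn2d was higher (0.67 ± 0.09, adjusted p = 0.000298) and 16 did not pass, with 3 higher when adjusted over the list alone. That list did not pass with an estimated correlation (adjusted p = 0.405), with the mean of all probes of a gene (adjusted p = 0.0542) or without SAMR1 replicate 3 or 5 or sedentary SAMP8 replicate 1, 2 or 4 (up to 0.068). It passed with those covariates (adjusted p = 0.00309) and in the block fit of the sedentary arrays (0.0412) and of all arrays (0.0352). Abcb1a, Slco1c1 and Cdkn2d each had a called neighbour among the 5 nearest tested genes on either side.

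Other called members of the fixed lists belonged to lists that did not pass in the unpaired fit. In the block fit of the sedentary arrays, chosen after the data were seen, 4 of them passed, and none of the 4 passed with an estimated correlation. Synaptic vesicle genes were higher (adjusted p = 0.0329, 0.0542 unpaired, 0.682 with an estimated correlation), and passed with the block over all arrays too (adjusted p = 0.0369). The other 3 did not pass with that block: heat shock genes, which were higher (0.0499, 0.0542 unpaired, 0.742 with an estimated correlation, 0.0639 over all arrays), and oligodendrocyte genes (0.0491, 0.0542, 0.775 and 0.055) and respiratory chain subunits (0.0499, 0.0549, 0.682 and 0.055), which were lower. The only called oligodendrocyte gene, Olig1, was higher (0.48 ± 0.11, adjusted p = 0.023), against the direction of its list, and lost its call with the covariates (0.60 ± 0.16, adjusted p = 0.139) and without SAMR1 replicate 1, 2 or 3 or sedentary SAMP8 replicate 1, 2 or 4 (up to 0.0687). Over all 42 lists, 29 of 872 measured genes were higher in SAMP8 and 10 were lower. Of 21 antigen presentation genes (camera adjusted p = 0.23), H2-Q4 was lower (-0.88 ± 0.13, adjusted p = 0.000436), as were H2-DMb1 (-0.79 ± 0.18) and H2-DMa (-0.41 ± 0.10), which load peptides on class II molecules, and 18 did not pass. Adjusted over the list alone, 3 were lower. H2-DMb1 lost its call without SAMR1 replicate 1, 3 or 4 or sedentary SAMP8 replicate 1, 4 or 5 (up to 0.0723) and with a floor at the 20th percentile (0.0523), and H2-DMa without any SAMR1 array, sedentary SAMP8 replicate 1, 2 or 4 or exercised SAMP8 replicate 2 or 4 (up to 0.118), in the block fit of the sedentary arrays (0.103) and of all arrays (0.0958), and with only the compared groups (0.0696). The complement component C4b was lower (-0.81 ± 0.11, adjusted p = 0.000133), as was the astrocyte marker Ntsr2 (-0.63 ± 0.09, adjusted p = 0.000529), whereas the reactive astrocyte gene Serpina3n was higher (0.70 ± 0.14, adjusted p = 0.00937). Also higher were Spink8, a marker of pyramidal cells (1.07 ± 0.13, adjusted p = 7.72e-05), the synaptic vesicle gene Syn2 (0.44 ± 0.09, adjusted p = 0.0115) and Chrna4, a nicotinic receptor subunit (0.75 ± 0.11, adjusted p = 0.000714), which gave -0.10 when all its probes were averaged. Of 20 insulin signalling genes (camera adjusted p = 0.34), Eif4ebp1, a repressor of translation, was lower (-0.78 ± 0.10, adjusted p = 9.38e-05), the transcription factor Foxo6 was higher (0.51 ± 0.12, adjusted p = 0.0315) and 18 did not pass, with the same counts when adjusted over the list alone. Foxo6 lost its call without SAMR1 replicate 3, 4 or 5 or sedentary SAMP8 replicate 1, 4 or 5 (up to 0.0886), in the block fit of the sedentary arrays (0.0707), with only the compared groups (0.0808) and with the covariates (0.69 ± 0.18, adjusted p = 0.109). Also lower were Dhcr7 of cholesterol synthesis (-0.48 ± 0.08, adjusted p = 0.00211) and the stress kinase Eif2ak3 (-0.59 ± 0.11, adjusted p = 0.0058). With the choroid plexus and meningeal covariates H2-DMa (-0.53 ± 0.15, adjusted p = 0.166), Serpina3n (0.66 ± 0.22, adjusted p = 0.302), Syn2 (0.37 ± 0.14, adjusted p = 0.453), Dhcr7 (-0.46 ± 0.13, adjusted p = 0.157) and Eif2ak3 (-0.68 ± 0.17, adjusted p = 0.0904) lost their calls. They kept 84.1% or more of their difference, with wider standard errors. Dhcr7 and Eif2ak3 also lost theirs with the mean of all probes of a gene (0.0647 and 0.986). The 3 antigen presentation genes, C4b, Syn2, Chrna4, Dhcr7 and Eif2ak3 each had a called neighbour in the genome. H2-DMa and H2-DMb1 lay in a group of 4 called genes with Col11a2 and H2-DMb2, all lower, and H2-Q4 in a group of 5 with Atp6v1g2, Tcf19, Vars2 and Flot1, 3 higher and 2 lower. Whether such members differed through their pathway or through their place in the genome was not tested. No member was called in the lists of amyloid and tau genes (27 measured, camera adjusted p = 0.761), antioxidant defence (27, 0.779), autophagy and lysosome (25, 0.478), glutamate receptors and the postsynaptic density (30, 0.925), Wnt signalling (30, 0.152), inflammatory cytokines (26, 0.818) or microglia markers (19, 0.345). Adjusted over the list alone, 3 Wnt genes were higher and 1 was lower, and the count was 0 in the other 6 of these lists. Of 36 subunits of the mitochondrial respiratory chain 1 was called, Cox6c (-0.44 ± 0.11, adjusted p = 0.0373), which lost its call without 9 of the arrays (SAMR1 replicates 1 to 4, sedentary SAMP8 replicates 1, 2, 3 and 5, exercised SAMP8 replicate 2; up to 0.11), with only the compared groups (0.0803) and with the covariates (-0.54 ± 0.16, adjusted p = 0.227).

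At an unadjusted p under 0.05, limma gave 1838 genes between the sedentary lines, against 820 expected by chance. The groups of arrays did not overlap in 688 genes, against 130 expected by chance.

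**Figure D3:**
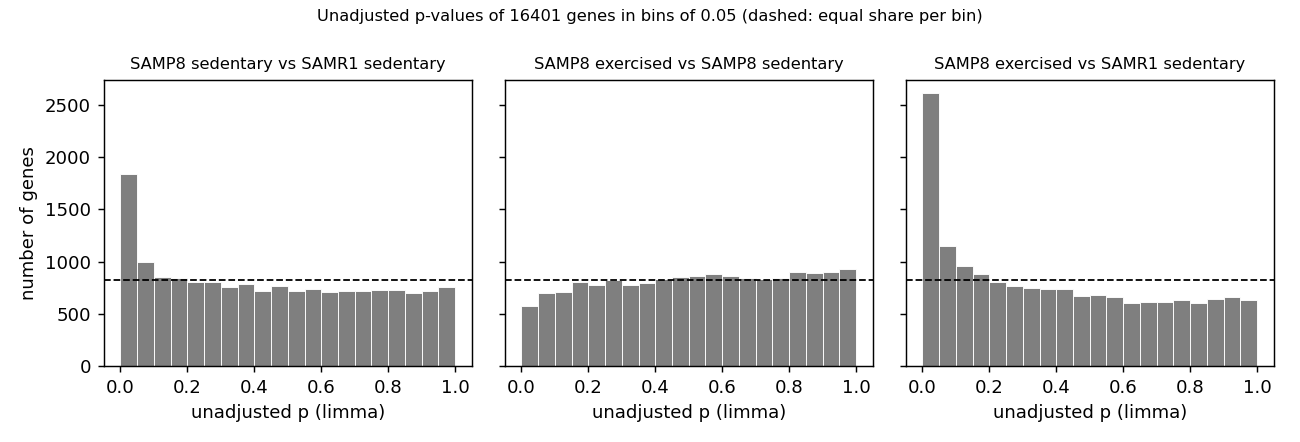
Number of the 16401 genes by unadjusted limma p, in bins of 0.05, for the 3 comparisons, with a dashed line at the equal share of each bin. The lowest bin held 1838 genes between the sedentary lines, 573 for exercise and 2608 between exercised SAMP8 and SAMR1.

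The second comparison asked what exercise changed in the hippocampus of SAMP8 mice. No single gene passed the threshold in limma, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 573 genes, fewer than the 820 expected by chance. The lowest p-values belonged to Efnb3, a ligand of Eph receptors (log2 difference -0.44 ± 0.09, SE, n = 5 per group), Map3k2, a kinase upstream of MAP kinases (-0.46 ± 0.10), Wipf3, an actin-regulating protein (0.42 ± 0.09), and Laptm5, a lysosomal protein of immune cells (-0.69 ± 0.16). The other lowest values were those of Ankmy2 (0.28 ± 0.07), Mir22hg (0.40 ± 0.11), Cpeb2, a regulator of translation (0.26 ± 0.07), Herc3 (0.29 ± 0.08), Tnrc18 (-0.53 ± 0.14) and Ahnak (-0.65 ± 0.17), none of which passed. The groups of arrays did not overlap in 72 genes, against 130 expected by chance. Without exercised SAMP8 replicate 3, 1 gene was called, Camk1d, a calmodulin-dependent kinase (-0.61 ± 0.07, adjusted p = 0.00672), which had a difference of -0.45 with all arrays and was singled out after its values were seen. In simulated data of the same size, with independent genes, the same test recovered 86% of genes changed 2-fold by exercise and 66% of those changed 1.5-fold.

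As groups, 7 of the 42 lists passed camera for exercise, all lower in exercised mice, and none had a called member, over all genes or adjusted over the list alone. None of the 7 passed with an estimated correlation, by fry or by the exact test after adjustment (adjusted p = 0.727 in the lowest case). Genes for cytosolic ribosomal proteins were lower in 30 of 31 members (camera adjusted p = 1.06e-08, adjusted p = 0.224 with an estimated correlation), with a mean of 14.47 ± 0.07 (SD, n = 5) in exercised and 14.58 ± 0.04 in sedentary mice (exact two-sided permutation p = 0.0238). Rpl23 (-0.24 ± 0.09, SE) and Rpl22 (-0.22 ± 0.09) had the lowest p-values of that list. Meningeal and fibroblast markers were lower in 18 of 18 members (camera adjusted p = 5.58e-10, adjusted p = 0.387 with an estimated correlation), with a mean of 9.19 ± 0.38 in exercised and 9.70 ± 0.35 in sedentary mice (exact two-sided permutation p = 0.0635). Col1a2 differed by -0.67 ± 0.23 and Col1a1 by -0.63 ± 0.23. Beside these markers, values were lower in 18 of 21 antigen presentation genes (camera adjusted p = 4.25e-06, adjusted p = 0.387 with an estimated correlation), such as H2-Q7 (-0.34 ± 0.11) and H2-Ab1 (-0.40 ± 0.15), and in 21 of 25 interferon-stimulated genes (camera adjusted p = 1.02e-05, adjusted p = 0.432 with an estimated correlation), such as Gbp2 (-0.37 ± 0.12) and Parp14 (-0.38 ± 0.13). Thalamus and habenula markers were lower in 16 of 18 members (camera adjusted p = 4.26e-06, adjusted p = 0.351 with an estimated correlation), such as Rgs16 (-0.40 ± 0.15) and Rora (-0.27 ± 0.10). Astrocyte markers were lower in 17 of 19 (camera adjusted p = 0.00642, adjusted p = 0.224 with an estimated correlation), such as Glul (-0.15 ± 0.09), whereas Serpina3n, the member with the lowest p, was higher (0.34 ± 0.14). Oligodendrocyte and myelin genes were lower in 17 of 22 (camera adjusted p = 0.00845, adjusted p = 0.653 with an estimated correlation), such as Mbp (-0.26 ± 0.11) and Trf (-0.19 ± 0.14). With the choroid plexus and meningeal marker means as covariates the interferon (adjusted p = 0.0891), antigen presentation (0.141) and astrocyte (0.125) lists lost their camera calls, and the ribosomal (0.00193), thalamus (0.00719) and oligodendrocyte (0.000162) lists passed. With the mean of all probes of a gene the astrocyte list lost its call (adjusted p = 0.107). The meningeal and interferon lists, lower here, were higher in sedentary SAMP8 than in SAMR1. Both comparisons use the same sedentary SAMP8 arrays with opposite signs, so high values on those arrays alone would give both results. The lists were not tested with these arrays split, so a reversal by exercise is not shown.

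Lists often studied in exercise did not pass. Neurotrophic and growth factors and their receptors were lower in 12 of 20 members (camera adjusted p = 0.81), adult neurogenesis and proliferation genes were split 11 and 11 (0.721), and immediate early genes were lower in 17 of 25 (0.183). Genes of mitochondrial biogenesis and glucose metabolism were higher in 19 of 25 (0.436), and respiratory chain subunits in 23 of 36 (0.701). Synaptic vesicle genes were higher in 19 of 23 (0.183), and antioxidant genes lower in 18 of 27 (0.298). The oligodendrocyte list also lost its call without sedentary SAMP8 replicate 1 or 4 or exercised SAMP8 replicate 4 or 5 (adjusted p up to 0.462), and the number of lists passing was 12 without sedentary SAMP8 replicate 5 or exercised SAMP8 replicate 5 and 11 without exercised SAMP8 replicate 3.

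The third comparison asked how far the exercised SAMP8 mice lay from sedentary SAMR1 mice, with line and exercise differing together. Of the 10 genes named for it, 9 were also named for the sedentary lines. Ccl19 was 51.6-fold higher in exercised SAMP8 (log2 difference 5.69 ± 0.25, SE, n = 5 per group, adjusted p = 3.69e-10), Adat2 5.85-fold (2.55 ± 0.10), Slc2a5 4.13-fold (2.05 ± 0.16), Rpusd4 3.46-fold (1.79 ± 0.10) and Mal2 3.22-fold (1.69 ± 0.11). Ppp1r1a was 6.23-fold lower (-2.64 ± 0.17), Metrn, a secreted factor of neurite growth, 3.99-fold (-2.00 ± 0.48, adjusted p = 0.0266), Enpp5 3.67-fold (-1.88 ± 0.13), Mcur1 3.39-fold (-1.76 ± 0.18) and Pcdh9 2.94-fold (-1.55 ± 0.18). Metrn lost its call without SAMR1 replicate 1, 2 or 4 or exercised SAMP8 replicate 1, 2 or 5 (up to 0.0797), with a variance trend and a robust prior (0.0612), the block over all arrays (0.0546), a floor at the 20th percentile (0.0633) and the choroid plexus and meningeal covariates (-1.32 ± 0.49, adjusted p = 0.292). Pcdh9 lost its call with the mean of all probes (-0.16, adjusted p = 0.461). In all 590 genes differed, 287 higher and 303 lower, against 2608 at an unadjusted p under 0.05. With the choroid plexus and meningeal marker means as covariates 316 differed.

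Of the 431 genes called between the sedentary lines, 348 (80.7%) were called here too, all in the same direction, 186 higher and 162 lower. Independent lists of these sizes, drawn without shared arrays, would share 4.2 and 3.53 genes. Both comparisons used the same 5 SAMR1 arrays. Simulated groups with no effect gave a correlation of 0.501 across genes, and the observed correlation across genes was 0.841. The simulated overlap was 0, but groups with no effect give almost no calls, so it does not measure what the shared arrays add. Genes are not independent replicates. The covariance was 0.0493, against 0.0105 in the simulations. When the SAMR1 arrays were split between the comparisons, in 20 splits, the overlap ran from 74 to 124 genes, from means of 209 and 169 calls, against 2 for independent lists, and the mean covariance was 0.0378.

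Of the lists, 7 passed camera between exercised SAMP8 and SAMR1, and none of them with an estimated correlation (adjusted p = 0.741 for each). Interferon-stimulated genes (6 of 25 called higher, 8 higher and 1 lower when adjusted over the list alone, camera adjusted p = 6.59e-05) and pericyte and smooth muscle markers (2 of 15 called higher, 7 when adjusted over the list alone, 6.59e-05) were again higher. Synaptic vesicle genes were higher too (1 of 23 called, 1 also when adjusted over the list alone, 0.00456). Their mean was 13.19 ± 0.01 (SD, n = 5) in exercised SAMP8 and 13.02 ± 0.10 in SAMR1 (exact two-sided permutation p = 0.00794, 0.0833 after adjustment). Antigen presentation genes (4 of 21 called lower, 6 when adjusted over the list alone, 6.59e-05), oligodendrocyte and myelin genes (5 of 22 lower and 1 higher, 9 and 1 when adjusted over the list alone, 0.000585), ribosomal proteins (1 of 31 lower, 1 also when adjusted over the list alone, 6.59e-05) and choroid plexus markers (0 of 22, 6.59e-05) were lower. The meningeal markers did not pass here (camera adjusted p = 0.0643), with a mean of 9.19 ± 0.38 in exercised SAMP8 and 8.88 ± 0.52 in SAMR1 (exact two-sided permutation p = 0.302).

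Among the 431 genes called between the sedentary lines, 246 (57.1%) had the opposite sign under exercise, that is, a value nearer to SAMR1. Both comparisons used the sedentary SAMP8 arrays with opposite signs, which alone gives opposite signs: when the 10 SAMP8 arrays were regrouped 100 times, the mean was 64.8% (SD 5.6), and 93 of 100 regroupings gave at least as high a share. With the sedentary arrays split between the comparisons, in 20 splits, the mean share was 49.5% (42.3% to 59.1%).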

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

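The tests of meningeal tissue as a source of the interferon and pericyte differences were chosen after the result was seen. The tests of other splits, second probes, chromosomal neighbours and shared arrays were written before it.

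The number of genes called between the sedentary lines was not reached by other groupings of the arrays. Of 100 splits of the 10 sedentary arrays, which ignored the pairs, 1, the real one, gave as many as 431 called genes. The highest other gave 7. Among the 16 splits that part all 5 pairs of same-numbered arrays the highest other gave 0, and 16 splits are too few for a share under 0.05. At an unadjusted p under 0.05, a split of SAMR1 replicates 1, 2 and 4 and SAMP8 replicates 2 and 4 against the rest gave 2332 genes, against 1838 for the real one, which points to a structure of the samples besides the lines. For exercised SAMP8 against SAMR1, 1 of 100 splits gave as many as 590 genes, and the highest other gave 6. For exercise the observed count was 0, which any split reaches (100 of 100), so this count could not have come out otherwise and decides nothing. The highest other split, with sedentary replicates 1, 2 and 3 and exercised replicates 3 and 5 together, gave 31, and the median of the others at an unadjusted p under 0.05 was 878 genes, against 573. At that p, 84 of 100 splits, the real one included, gave at least as many genes as the real one. The 31 was the highest of many splits with a median of 0, so a structure of the SAMP8 arrays across the groups was not shown.

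Genes that differed between the lines lay beside each other more often than random genes, 52.6% against a 95th percentile of 27.7%. A candidate explanation is blocks of the genome that differ between these inbred lines, and the test, which could have come out within the random draws, went with it. Keeping 1 gene per symbol stem, so that neighbouring members of a family count once, left 50% against 23.5% at random, which argues against gene families as the whole source. Sequence variants under single probes stay open. A second probe was used if its mean was above the median gene and at least 1 log2 unit from the first, with no check of sequence. Of 27 called genes with one, 19 (70.4%, exact binomial 95% interval 49.8% to 86.2%) differed in the same direction on it, a range that holds both chance and a clear majority. At an unadjusted limma p under 0.05, 16 differed in the same direction and 5 in the opposite one, so for those 5 the direction depended on the probe. Differences in regulation between the lines that do not come from such blocks also stay open, as untested.

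The interferon-stimulated and pericyte genes were higher in sedentary SAMP8, as were the meningeal markers. Meningeal tissue in the dissected samples may account for part of these differences. Within the sedentary groups the slope on the meningeal mean was 0.256 (95% interval -0.0147 to 0.526) for the interferon list. For the pericyte list it was 0.215 (-0.136 to 0.567), and both intervals held 0, so movement together from array to array was not shown. In the 10 sedentary arrays, the meningeal mean as a covariate left 53.6% of the interferon difference (0.45, 95% interval 0.20 to 0.71, before, and 0.24, -0.07 to 0.55, after). It left 61.8% of the pericyte difference (0.46, 0.17 to 0.75, before, and 0.29, -0.11 to 0.69, after). Within the pairs of same-numbered sedentary arrays, also fitted only after that result, it left an interferon difference of 0.77 (0.03 to 1.51). The pericyte difference left was 0.16 (-1.16 to 1.48). The interferon value lay above the 0.45 without the covariate because the fitted slope was negative (-0.388, -1.25 to 0.48), with an interval that held 0. These values rest on 5 pairs, all with a meningeal difference of 0.39 or more. They are read at a meningeal difference of 0, outside that range, so they do not decide the question. Without pair 1, 2, 4 or 5 the interferon interval held 0 (from -0.45, -0.61, -0.03 and -0.44), and without pair 3 it was 0.56 to 0.73. Meningeal tissue and a difference of the lines cannot be told apart here, since the markers differ with the line and the pairs are few. The list also holds fibroblast markers, so its mean does not measure meningeal tissue alone. Fits looked at only after that result left 68.9% and 62.6% over all 15 arrays (0.31, 0.03 to 0.60, and 0.29, 0.01 to 0.57). Between exercised SAMP8 and SAMR1 they left 93.1% and 82.3% (0.27, 0.09 to 0.46, and 0.34, 0.08 to 0.61), with a meningeal difference of 0.31 (exact two-sided permutation p = 0.302).

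Some arrays stood far from the other 4 of their group, by a gap over range above Dixon's critical value of 0.710. Chance alone puts about 1 in 20 groups past this value: 3 of 45 groups of marker means were past it, against 2.25 expected, and 16 of 243 groups of named genes, against 12.2 expected. Striatum markers were 1.32 higher on the log2 scale on SAMR1 replicate 5 than on the other SAMR1 arrays (ratio 0.929). All 15 measured markers were higher on it than on each of the other 4, among them Penk by 2.73, Rgs9 by 2.53, Drd2 by 2.45 and Drd1 by 2.04. Without that array 346 genes were called between the sedentary lines and 545 between exercised SAMP8 and SAMR1. Dentate gyrus granule cell markers were 0.45 higher on sedentary SAMP8 replicate 3 (ratio 0.912). Microglia markers differed by -0.28 on SAMR1 replicate 2 (0.759).

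Of the named genes, 16 had such an array. Metrn differed by -2.43 on sedentary SAMP8 replicate 3 (ratio 0.770) and Laptm5 by -0.65 on the same array (0.785). Rgs5 was 0.36 higher on sedentary SAMP8 replicate 1 (0.816), and Cpeb2 differed by -0.22 on sedentary SAMP8 replicate 5 (0.720). Among SAMR1 arrays, Eif2ak2 differed by -0.44 on replicate 5 (0.900), Usp18 by -0.79 on replicate 1 (0.826), Eif4ebp1 by -0.34 on replicate 2 (0.812) and Mbp by -0.18 on replicate 3 (0.898). Ankmy2 was 0.08 higher on SAMR1 replicate 1 (0.732), and Abcb1a 0.23 higher on SAMR1 replicate 4, the only one of the group above the floor (ratio 1). Among exercised SAMP8 arrays, Slc2a5 differed by -0.35 (0.777) and Thbs4 by -0.84 (0.867) on replicate 4. Usf1 was 0.18 higher on exercised replicate 5 (0.735) and Olig1 0.32 higher on exercised replicate 2 (0.775). On exercised replicate 1, C4b differed by -0.31 (0.793) and Ntsr2 was 0.31 higher (0.712).

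Features without a single gene symbol were used in no comparison of genes. Of 6511 such features, 105 were called between the sedentary lines, 62 higher and 43 lower in SAMP8. The widest of these differences, 7.48 ± 0.46 (SE, adjusted p = 5.9e-08, higher in SAMP8), was larger than that of Ccl19, and in exercised SAMP8 against SAMR1 it was 7.72 ± 0.46. Between exercised SAMP8 and SAMR1 115 were called, 61 higher and 54 lower, and for exercise 0.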

How the results depend on the processing

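Cyclic loess, the sedentary arrays alone with a replicate block and the marker covariates were chosen after seeing the data. Median centring and quantile normalization moved almost nothing, because the deposited values were already quantile normalized, and they say nothing about stability.

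Between the sedentary lines, 431 genes were called. There were 273 with at least 1.5-fold, 685 counted as probes, 648 in the sedentary arrays alone with the replicate block and 179 with choroid plexus and meningeal covariates. The replicate block over all arrays gave 460, and the other settings gave 337 to 594. Leaving out 1 array gave 336 to 472. The share of higher calls was 44.1% with the covariates against 55.7%. For exercised SAMP8 against SAMR1 (590), there were 302 with at least 1.5-fold, 915 at an adjusted p under 0.10, 1056 counted as probes and 316 with the covariates, and 406 to 598 without 1 array. For exercise the count was 0 under every setting except without exercised SAMP8 replicate 3 (0 to 1 over the arrays left out).

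The pairing check for exercise (r from -0.098 to 0.35, 1 of 5 pairs over 0.1) and for exercised SAMP8 against SAMR1 (0.012 to 0.37, 2 of 5) gave no pairing over all numbers. In these, 1 and 2 of 5 arrays were closest to their own number. Replicate 4 was closest to its own number in each comparison (r = 0.52 between the sedentary lines, 0.35 for exercise, 0.37 for exercised SAMP8 against SAMR1). Shared structure by number was thus not confined to the sedentary arrays. The replicate block gave 0 genes for exercise and 726 for exercised SAMP8 against SAMR1, against 590 without it. In the paired comparison, the block fit of the sedentary arrays, which was not planned, ended the endothelial call and 4 named genes' calls. It added 4 lists: synaptic vesicle genes (adjusted p = 0.0329, 0.682 with an estimated correlation), oligodendrocyte genes (0.0491, 0.775), heat shock genes (0.0499, 0.742) and respiratory chain subunits (0.0499, 0.682). The planned block over all arrays kept the endothelial call (0.0498), added synaptic vesicle genes alone (0.0369) and ended 6 named genes' calls between these lines.

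Of 42 lists, 7 passed between the sedentary lines, 11 with only the compared groups, 8 with the covariates, 0 with an estimated correlation, 2 by fry, and 5 to 13 without 1 array (13 without SAMR1 replicate 2). For exercise 7 passed, 4 with the covariates, 0 with an estimated correlation, 0 by fry, and 6 to 12 without 1 array. With the covariates the choroid plexus and meningeal lists were left out.

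The share of genes called between the sedentary lines with the opposite sign under exercise was 57.1%, 68.2% with the covariates, 55.8% to 62.4% without 1 array, and a mean of 49.5% (42.3% to 59.1%) with the sedentary arrays split. That split also left fewer arrays and a mean of 197 called genes, so the cause of the turn was not separated. Clustering was 49.2% to 53.6% without 1 array and 34.3% with the covariates, which left fewer called genes, and passed its permutation test in every setting. Chrna4 turned to -0.10 with the mean of all probes. Of 1606 values of 60 genes named between the sedentary lines, 1415 kept direction and side of the threshold, 190 lost the call and 1 turned. For exercised SAMP8 against SAMR1 249 of 260 kept both and 11 lost the call. For exercise all 622 kept both, but no named gene was called there, so none could lose a call. All these counts take in median centring and quantile normalization, which hardly change the values, and leaving out arrays of the group not compared. The shares kept are thus no measure of stability. The causes of these changes were not tested. A floor at the 20th percentile ended 11 named genes' calls, of which 8 had the same difference and 3 (Oas2, Oas1a and Usp18) a smaller one.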

Other observations

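The tests in this part were chosen before the result was seen, apart from the block fit of the sedentary arrays.

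A few further groups differed between the sedentary lines by their mean per array at an unadjusted p under 0.05, without passing over all lists. The exact test used for this ignored the pairing of the arrays. Neocortex markers, which hold Ccn2, had a mean of 9.39 ± 0.07 (SD, n = 5) in SAMP8 and 9.26 ± 0.01 in SAMR1, with 14 of 19 members higher (exact two-sided permutation p = 0.00794, 0.111 after adjustment over 42 lists, camera adjusted p = 0.17). Genes of adult neurogenesis and proliferation were higher in 15 of 22 members (exact two-sided permutation p = 0.0238, 0.25 after adjustment, camera adjusted p = 0.145), and GABA receptor subunits were lower in 10 of 14 (exact two-sided permutation p = 0.0317, 0.267 after adjustment, camera adjusted p = 0.324). Other lists had most members higher but did not differ by their mean per array. Heat shock genes and chaperones were higher in 17 of 21 (camera adjusted p = 0.0542, exact two-sided permutation p = 0.127). Circadian clock genes were higher in 16 of 20 (0.114 and 0.0873) and genes of endoplasmic reticulum stress in 17 of 23 (0.2 and 0.206). None of these lists passed in the unpaired fit. The heat shock list passed in the block fit of the sedentary arrays (adjusted p = 0.0499), but not with the block over all arrays (0.0639) or with an estimated correlation (0.742). The glucocorticoid targets (camera adjusted p = 0.84), insulin signalling genes (0.34) and chromatin modifiers and sirtuins (0.419) did not pass either.

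The shift of genes called between the sedentary lines towards SAMR1 under exercise was tested for the arrays that both comparisons share. With the sedentary SAMP8 arrays split between the comparisons, the mean share of genes with the opposite sign was 49.5%, and 93 of 100 regroupings gave at least the observed 57.1%. The covariance of the comparisons across genes was -0.00494, against a mean of -0.0121 in the regroupings and -0.0119 expected from the shared arrays alone, and with the arrays split it was 0.00593. The share of opposite signs was thus no higher than the regroupings gave. The covariance was less negative than their mean, and 99 of 100 regroupings had one at least as negative. Neither the regroupings nor the expected value took in the pairing of sedentary SAMR1 and SAMP8 arrays, so the source of the opposite signs was not settled. A reversal of strain differences by exercise was not detected in these arrays.

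Along the first principal component, with 21.4% of the variance over all genes, the 5 SAMR1 arrays lay from -32.2 to -5.21 and the 10 SAMP8 arrays from -3.85 to 18.9. The second component had 16.7%, with SAMR1 replicate 5 at 27.7 and sedentary SAMP8 replicate 4 at -26.5 at its ends. Replicate 4 was the lowest of its group on it in SAMR1 (-13.7) and exercised SAMP8 (-19.7) too.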
